A study of Mus musculus with 9 samples.

How the data were processed

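RNA sequencing libraries were made from total RNA of splenic NK cells of C57BL/6 mice, purified on RNeasy columns and reverse transcribed with SuperScript II, per the labels' protocols. The 9 libraries were 3 of Id2-null NK cells, 3 of WT NK cells and 1 each of the wild-type populations Immature, M1 and M2. Per the labels, samples 1 to 6 were grown in IL-15 for 7 days and samples 7 to 9 were sorted from spleen and used directly. The labels do not number the samples otherwise. They were taken in listed order, so that the 6 libraries with a genotype and replicate number are the cultured ones, and this assignment is a limit of every comparison. The markers by which Immature, M1 and M2 cells were sorted, the way in which Id2 was deleted, and the sex and number of animals are not given in the sources used here.

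The deposited files held raw counts per Entrez gene and a gene length in bases, per the file headers. Reads were aligned with Subread and counted with featureCounts against GRCm38 (mm10), and limma was named as a further tool, per the submitters' processing notes. Versions, the annotation, the strand setting, the handling of reads with several matches and the filters applied are not given in the sources used here. All values were whole numbers, with 27179 genes in each library. Gene symbols and coordinates came from a RefSeq table of GRCm38.p6 for 25275 Entrez identifiers and from GENCODE for 18, and 1886 had no symbol. Total counts were 4476563, 4628289 and 4482468 in Id2-null replicates 1 to 3, 4657719, 4729566 and 4831831 in WT replicates 1 to 3, 4128414 in Immature, 4462803 in M1 and 4500825 in M2. The most abundant gene took at most 1.47% of a library. A count of 0 was read as a level of up to 3 counts, and intervals for the libraries without replicates were exact Poisson 95% intervals. Both cover counting error only, since reads without molecular identifiers are not independent molecules. Genes with near-identical copies, such as granzyme, Ly49 and Ly6 genes, and antisense pairs such as Xist and Tsix are uncertain where reads could be split between them or strand was not used.

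Id2-null and WT cultures were compared in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 11022, and libraries were scaled by TMM. A negative binomial model with genotype alone was tested by quasi-likelihood, with Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 0.209, and 1613 genes had an unadjusted p under 0.05. CPM are TMM-scaled unless given as counts. Levels are means with SD over 3 libraries per genotype. "Rose" and "fell" are used for called genes, and values stand without such a verb for others.

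A set of 35 gene lists with 497 members was written before the data were examined, covering E proteins and Id proteins, cytotoxicity, maturity, receptors, cytokine signalling, related lineages, metabolism, stress, sex-linked genes and markers of other blood and stromal cells. Of the members, 494 matched a gene in the files, and Zfp683, Hbb-bt and Ahsp did not. The 28 lists with at least 3 tested members were tested with camera in limma 3.58.1 on voom values at a preset correlation of 0.01, with adjustment over these lists. Of these lists, 2 were called higher and 5 lower. With an estimated correlation 0 lists passed in camera (lowest adjusted p = 0.0829, with 6 at unadjusted p under 0.05). The estimate was 0.000193 for cytotoxic effectors, -0.0243 for the ILC1 list and -0.0494 for the sex-linked list, each under the preset 0.01. Correlation among members therefore does not account for the loss of those calls, and its cause was not tested. With fry 7 lists passed. The fry calls included the E protein and Id list, which holds the deleted gene Id2, and not the cell cycle list, and the other 6 were also camera calls. List medians and means are of voom log2 fold changes. For each list the count of members called when adjusted over the list alone stands beside the count over all genes.

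The genes to be named were set by a rule. They were the E protein and Id list, the 10 largest log2 folds each way among called genes with a mean log2 CPM of at least 4 and no overlap between genotypes, and up to 4 called members per list by adjusted p. In lists without a call the 2 members with the highest expression were taken. Il2rb, Il2rg, Socs3, Tcf7, Il7r, Eomes, Tbx21, Gzmb, Prf1, Klrg1, Cd27 and Itgam were included whatever their result. Some of the genes that the rule took are not reported here. Between the sorted libraries the rule took 10 genes each way by log2 ratio, with at least 20 CPM in the highest library and M1 between the others. List members named only for a call under the replicate block, Ccr7, Ly6c2, Itgae, Uty, S100a8, Lyz2, Cd79a, Vegfa, Bnip3 and Egln3, the list members given for the sorted libraries and the genes in the closing section's first paragraphs were chosen after their values were seen. The main test, the lists, the rule and the alternatives were set before the data were examined, apart from leaving out replicate 3 of both genotypes and leaving out X- and Y-linked genes, which were added afterwards.

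The Immature, M1 and M2 libraries have no replicates and were described by counts, CPM and log2 ratios with a prior of 2 counts. The median of each list was placed among 10000 random lists of the same size matched on mean expression. For a comparison with the cultures, the 200 genes each way with the largest Immature to M2 ratio and at least 10 CPM in the higher library formed 2 sets, which were tested with camera. Correlations of fold changes are across genes, which are not independent replicates.

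Both genotypes carry replicate numbers 1 to 3, and whether the numbers pair the libraries was checked before any calls were compared. The deviations of same-numbered libraries from their group means correlated at 0.352, 0.241 and 0.417 across genes for replicates 1, 2 and 3, and each library correlated best with its own number in the other genotype. Deviations cancel out within a genotype, so a shift shared by replicate 3 alone raises the correlations among replicates 1 and 2. Across numbers 1 and 2 the correlations were 0.189 and 0.136, so the pairing of these 2 numbers is only weakly shown. The pairing comes from these values, since the labels do not say what a number stands for. Values with the replicate number as a block are therefore printed where they change the call of a named gene or a list, or move a count of calls by over 1.5 times. Replicates differed by more than counting noise: the chi-square per degree of freedom was 6.14 for WT replicates 1 and 2 and 13.6 and 16.2 against WT replicate 3. It was 5.09 for Id2-null replicates 1 and 2 and 28.6 and 28.3 against Id2-null replicate 3.

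The tests were tested on simulated data of the Id2-null and WT comparison, 10 times, on 10889 to 10926 genes of which 200 changed. Of 2-fold changes 55.2% were recovered and of 4-fold changes 91.8%, with 0 errors of sign. False calls made up 9.66% of the calls, and 17.1% with the replicate block, which recovered 54.1% of 2-fold changes. Unchanged lists gave 0 camera tests at p under 0.05, but the simulated genes were drawn independently of each other. That result therefore cannot show how camera behaves on lists with correlated members. The simulated counts also held no effect shared by a replicate number, so the rates of the block do not describe paired data. Alternatives tried were RLE, upper quartile and no scaling beyond library size, no expression filter, a filter at 1 CPM, DESeq2 1.42.0, limma voom, the replicate block, each replicate left out in turn, all 9 libraries in the fit and an adjusted p under 0.01. For the sets and the sorted libraries they were 100 or 500 genes each way, a minimum of 1 CPM, a prior of 0.5 counts, library size alone and a minimum of 5 CPM. Analyses that need the reads, such as exon use at Id2 or strand, were left out because the files hold gene totals only.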

Results

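Gene expression was measured by RNA sequencing in natural killer (NK) cells from the spleen of C57BL/6 mice. NK cells are innate lymphocytes that kill infected or transformed cells and need the cytokine interleukin-15 (IL-15) to survive. The series asked how the helix-loop-helix protein ID2 sets the fate of NK cells and their sensitivity to IL-15. Id2-null and wild-type (WT) NK cells were grown for 7 days in IL-15, with 3 libraries per genotype. A further 3 wild-type libraries, 1 each from populations named Immature, M1 and M2, came from cells sorted from spleen with no culture. Total counts ran from 4128414 in the Immature library to 4831831 in WT replicate 3, and each library had counts in 13888 to 14432 genes. A count of 0 therefore allows a level of up to 0.62 to 0.73 counts scaled to library size (CPM), by a limit of 3 counts that covers counting error only. The labels do not say whether replicates came from separate mice or cultures, so p-values measure only the spread between these libraries, which may be technical.

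Id2, the targeted gene (Entrez 15902, protein-coding, chromosome 12, positions 25093799 to 25096092 in GRCm38), was low in every library labelled Id2-null. Its counts there were 56, 113 and 44, against 1958, 1925 and 1945 in the WT libraries. The level fell from 410.8 ± 17.3 CPM in WT (SD, n = 3) to 15.8 ± 8.19 CPM in Id2-null cells (SD, n = 3). The fold change was -4.70 on the log2 scale (SE 0.35, adjusted p = 0.00116, edgeR quasi-likelihood test), which left 3.84% of the WT level, and 2.29 to 6.09% by library. Which part of the gene was deleted is not given in the sources used here. In the sorted populations Id2 stood at 742 CPM in Immature, 877 CPM in M1 and 1140 CPM in M2 cells.

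Among the other members of the fixed E protein and Id list, Id3 and Tcf12 rose in Id2-null cells. E proteins are basic helix-loop-helix transcription factors, and Id proteins bind them and keep them off DNA. Id3 (chromosome 4, positions 136143822 to 136145392), which encodes another Id protein, went from 0.794 ± 0.876 to 56.9 ± 10.1 CPM (SD, n = 3 each). Its log2 fold change was 6.14 (SE 0.55, adjusted p = 0.00202, edgeR). Tcf12, which encodes the E protein HEB, rose from 173 ± 6.42 to 257 ± 17.0 CPM (log2 fold change 0.57, adjusted p = 0.0265). Tcf3, which encodes E2A, did not pass the test at 123 ± 15.9 against 108 ± 6.76 CPM (adjusted p = 0.598). Tcf4, which encodes E2-2, stood at 99.5 against 69.1 CPM with adjusted p = 0.248, and at adjusted p = 0.031 with the replicate number as a block. Of the 5 members tested, 2 were higher and 1 was lower, and 2 and 2 when adjusted over the list alone. The list had a median log2 fold change of -0.18, a mean of 0.36 and a camera adjusted p of 0.774 (adjusted p = 0.878 with an estimated correlation). Fry gave adjusted p = 0.0362 for lower, but the list holds Id2, whose level the genotype sets. The Tcf12 call was lost when WT replicate 1, 2 or 3 or Id2-null replicate 1 or 2 was left out, with adjusted p between 0.0708 and 0.133.

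**Figure D1:**
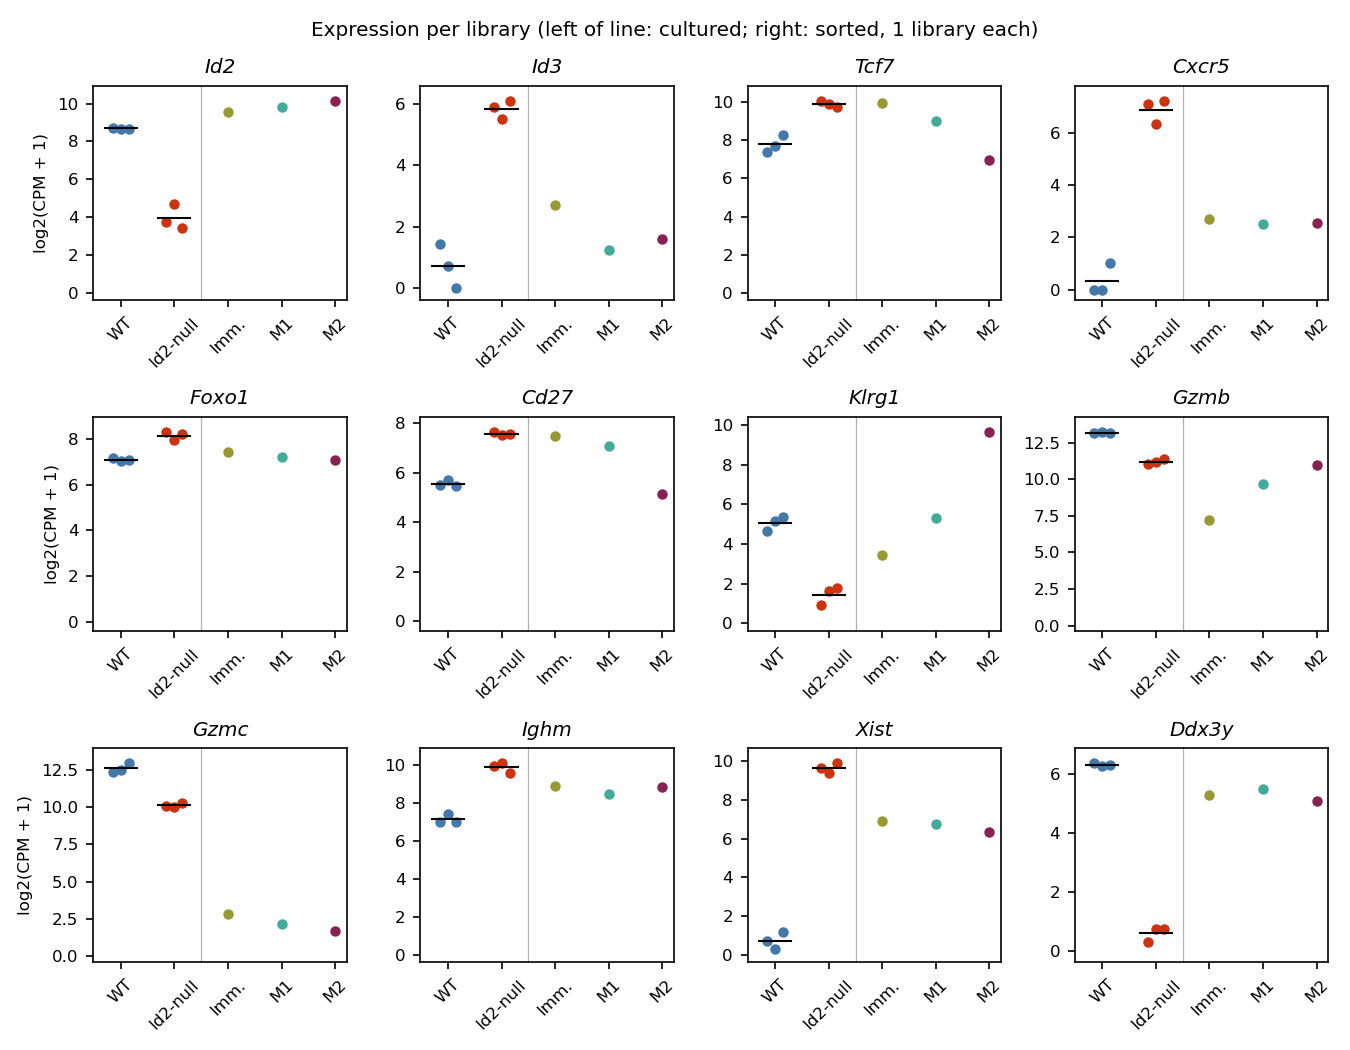
Expression of 12 genes in each library, as log2 of CPM plus 1 on the y axis, with CPM by library size alone, and with WT and Id2-null cultures (3 libraries each, black line at the mean) left of the grey line and the sorted Immature, M1 and M2 populations (1 library each) right of it. Id2 was low and Id3, Tcf7, Cxcr5, Foxo1, Cd27, Ighm and Xist were high in all 3 Id2-null libraries, while Klrg1, Gzmb, Gzmc and Ddx3y were high in all 3 WT libraries.

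Over the whole transcriptome, 377 of 11022 genes tested differed between Id2-null and WT cultures, 210 higher and 167 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 148 were over 2-fold higher and 117 over 2-fold lower. Among the genes with the largest rise, Cxcr5 (chromosome 9, positions 44511787 to 44526444), the receptor for the B-follicle chemokine CXCL13, went from 0.335 ± 0.581 to 120 ± 33.2 CPM (SD, n = 3 each). Its WT counts were 0, 0 and 5. Drc1, Arl5c, Tbxa2r (the thromboxane A2 receptor), Cd163l1, Nsg2, Npas2 and Adgrl2 also rose, from WT means of 0.722 to 4.09 CPM to Id2-null means of 30.2 to 70.4 CPM. Among the genes with the largest fall were the granzymes Gzmg, Gzmd and Gzme. Entpd1, which encodes the ectonucleotidase CD39, fell from 80.3 ± 32.0 to 2.16 ± 0.852 CPM (adjusted p = 0.00119). WT replicates 1 to 3 varied widely for Mmp9, a gelatinase (55.5, 31.4 and 6.64 CPM), and for Scin, an actin-severing protein (38.6, 28.2 and 132.8 CPM). Mmp9 fell from 31.2 ± 24.4 to 0.446 ± 0.225 CPM and Scin from 66.5 ± 57.65 to 2.58 ± 0.393 CPM, with adjusted p of 0.0479 and 0.0461. With limma voom these 2 calls were lost, at adjusted p of 0.233 and 0.108, and with no expression filter, at 0.121 and 0.112. Both were also lost without Id2-null replicate 1, 2 or 3 or WT replicate 1, and Mmp9 without WT replicate 2 or with all 9 libraries in the fit (adjusted p 0.055 to 0.24). Drc1 and Npas2 were not called without WT replicate 1 (adjusted p 0.0547 and 0.061).

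Transcripts of the sex chromosomes divided the libraries in the same way as the genotype. Xist, the X-inactivation RNA that is expressed in female cells, stood at 817 ± 117 CPM in Id2-null and 0.691 ± 0.497 CPM in WT libraries (SD, n = 3 each). The Y-linked genes Ddx3y, Eif2s3y and Kdm5d stood at 77.9, 82.4 and 52.8 CPM in WT and at 0.512, 1.04 and 0.511 CPM in Id2-null libraries. The list of 5 sex-linked genes had 1 higher and 4 lower, also when adjusted over the list alone (camera adjusted p = 0.000214, and adjusted p = 0.0829 with an estimated correlation), with Uty at adjusted p = 0.0292. Uty was not called with the replicate block (0.065), with no expression filter (0.0685), or without Id2-null replicate 1 or 2 or any WT replicate (0.0772 to 0.129). No library separated sex from genotype, which holds for every gene and list compared here between the cultures. Genes on the X chromosome gave 12 of the calls and genes on the Y chromosome 4, and 361 lay elsewhere. Each of the 377 genes had WT and Id2-null values that did not overlap, as did 20.4% of all genes tested, where chance gives 10%. With the replicate number as a block, 452 genes were higher and 383 lower. The counts were 121 in all without WT replicate 1, 175 without Id2-null replicate 1, 180 without Id2-null replicate 2, 183 without WT replicate 2 and 662 without Id2-null replicate 3. The higher calls went from 210 to 134 without WT replicate 3. Replicate 3 of both genotypes stood apart from replicates 1 and 2, and leaving out both gave 571 higher and 494 lower.

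**Figure D2:**
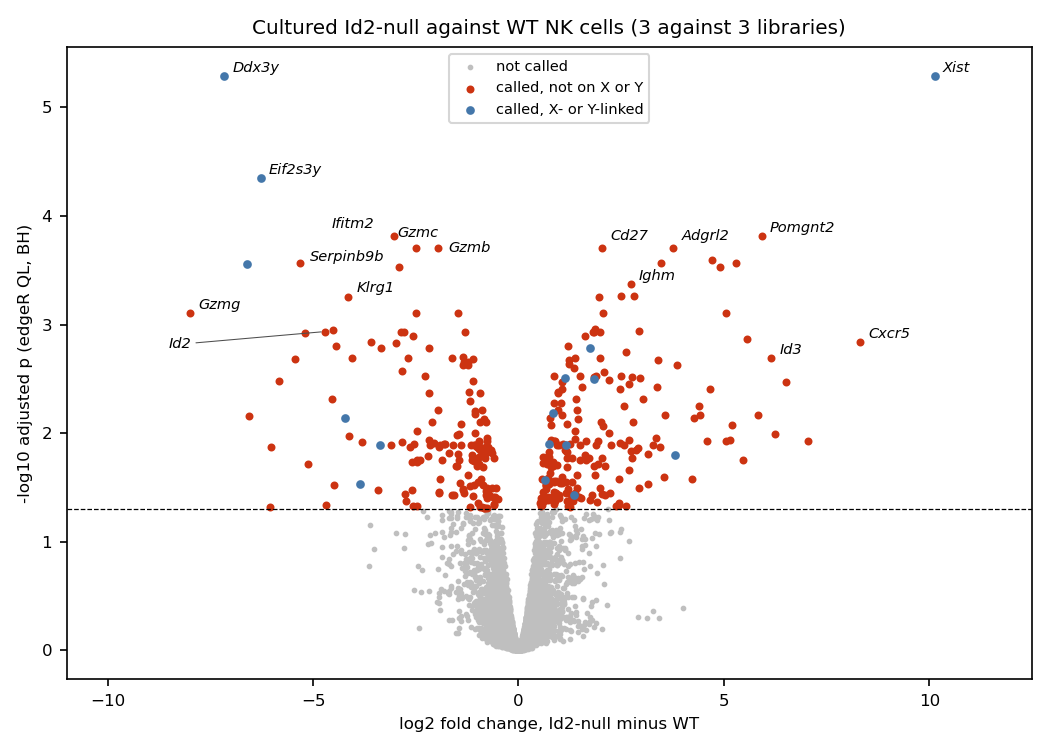
Log2 fold change of Id2-null minus WT cultures (x axis) against the -log10 adjusted p of the edgeR quasi-likelihood test (y axis) for 11022 genes, 3 libraries against 3. Red and blue points are the 377 called genes off and on the sex chromosomes, the dashed line marks an adjusted p of 0.05, and Xist and Ddx3y have the smallest adjusted p.

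Of 19 cytotoxic effector genes tested, 6 fell and 1 rose in Id2-null cells, and 8 fell and 1 rose when adjusted over the list alone. The list was lower by camera at the preset correlation (adjusted p = 5.69e-08) but did not pass with an estimated correlation (adjusted p = 0.0829). The estimate for this list, 0.000193, lay under the preset 0.01. Gzmb, the granzyme that triggers caspases in target cells, fell from 9282 ± 476 to 2393 ± 190 CPM (SD, n = 3 each), a log2 fold change of -1.96 (SE 0.12, adjusted p = 0.000197). Gzmc fell from 6256 ± 1187 to 1119 ± 47.4 CPM (log2 fold change -2.48, adjusted p = 0.000197). Serpinb9, an inhibitor of granzyme B, fell from 535 ± 93.3 to 211 ± 9.94 CPM. Gzmd and Gzme, which lie with Gzmb and Gzmc on chromosome 14, fell from 968 and 442 CPM to 10.2 and 7.64 CPM. Gzmg, which lies there too but was not in the list, fell from 287 to 1.10 CPM. These granzyme genes are close copies of each other, so how their shared reads were counted is uncertain. Gzmm, on chromosome 10, rose from 8.29 ± 1.89 to 63.2 ± 19.1 CPM (adjusted p = 0.00114). Prf1, which encodes the pore-forming protein perforin, stood at 1511 ± 784 against 524 ± 205 CPM with adjusted p = 0.292, and at adjusted p = 0.00563 with the replicate block. Without WT replicate 3 the Prf1 difference passed the test (adjusted p = 0.0466), and that of Gzmd did not without Id2-null replicate 2 (adjusted p = 0.0538) or without replicate 3 of both genotypes (0.0834). With the replicate block 8 members were lower and 2 higher, the second of these being Gzmk (6.88 against 18.9 CPM, adjusted p = 0.54, and 0.008 with the block).

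The mature NK list had 4 of its 13 tested members lower and 1 higher, and 6 lower and 1 higher when adjusted over the list alone. Camera gave adjusted p = 5.69e-08 at the preset correlation and adjusted p = 0.0829 with an estimated correlation. With the replicate block 7 members were lower, Prf1, Tbx21 and Prdm1 besides, the last at 85.4 against 31.2 CPM (adjusted p = 0.506, and 0.00175 with the block). The member that rose was Ly6c2, at 61.5 against 173 CPM (adjusted p = 0.0176, and 0.0805 to 0.116 without Id2-null replicate 1 or 2 or WT replicate 1). Klrg1, an inhibitory receptor of mature NK cells, fell from 32.8 ± 7.20 to 1.83 ± 0.791 CPM (adjusted p = 0.000553). Serpinb9b fell from 27.8 ± 4.84 to 0.672 ± 0.398 CPM, and Itgb2, the integrin chain that pairs with CD11b, from 710 ± 103 to 388 ± 32.7 CPM. Itgb2 was not called without Id2-null replicate 1 or 2 or WT replicate 1 or 2, with adjusted p from 0.0557 to 0.0841. Itgam, which encodes CD11b, did not pass the test at 86.6 ± 46.5 against 31.9 ± 28.8 CPM. Tbx21, which encodes the transcription factor T-bet, stood at 142 ± 19.8 against 93.5 ± 9.15 CPM (adjusted p = 0.0566). It passed with the replicate block (0.0071), with DESeq2 (0.0143), with no expression filter (0.0316) and without Id2-null replicate 3 (0.0138). The list of NK receptors had 4 of 28 members lower and none higher (camera adjusted p = 0.252), and 4 lower and 1 higher when adjusted over the list alone. Klrb1b fell from 217 ± 13.1 to 85.7 ± 14.4 CPM, Klra9 from 128 to 70.8 CPM, Klra1 from 77.6 to 44.8 CPM and Klri1 from 15.2 to 7.02 CPM. Klra genes encode Ly49 receptors and are near-identical copies, so their counts are uncertain. Klra1 and Klri1 were not called without Id2-null replicate 1 or 2 or any WT replicate, nor Klra9 without Id2-null replicate 1 or 2 or WT replicate 1 or 3 (adjusted p 0.0618 to 0.161). Limma voom did not call Klra1 either (adjusted p = 0.0554), nor did edgeR with library sizes alone as scaling (0.0604).

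In the immature NK list 5 of 15 members rose, 0 fell, and 6 rose when adjusted over the list alone. Camera gave adjusted p = 1.24e-06 at the preset correlation and adjusted p = 0.0829 with an estimated correlation. Cd27, a costimulatory receptor of less mature NK cells, rose from 46.7 ± 5.75 to 190 ± 12.6 CPM (SD, n = 3 each), a log2 fold change of 2.03 (SE 0.13, adjusted p = 0.000197). Cxcr3, a chemokine receptor encoded on the X chromosome, rose from 86.8 ± 17.7 to 290 ± 45.8 CPM, and Ltb, which encodes lymphotoxin beta, from 143 ± 25.1 to 324 ± 50.2 CPM. Tcf7, which encodes the transcription factor TCF-1, rose from 227 ± 70.3 to 963 ± 135 CPM (log2 fold change 2.08, SE 0.23, adjusted p = 0.00272). In the T-lineage progenitor list 7 of 14 members rose and 0 fell, and 9 rose and 2 fell when adjusted over the list alone. Camera gave adjusted p = 9.23e-07 at the preset correlation and adjusted p = 0.083 with an estimated correlation. Foxo1, a transcription factor of quiescent lymphocytes, rose from 135 ± 8.69 to 282 ± 35.6 CPM (adjusted p = 0.00335). The T cell marker list had 0 of 6 members called by edgeR, with 2 at unadjusted p under 0.05 and 1 called by DESeq2 and 1 by limma voom (camera adjusted p = 0.254). Under the replicate block Cd3d was called higher (29.0 against 121 CPM, adjusted p = 0.00142) and Cd3e lower (40.8 against 15.4 CPM, 0.0159). Trafficking receptors went both ways, with 4 of 16 higher and 2 lower, and 4 and 3 when adjusted over the list alone (camera adjusted p = 0.233). Cxcr6, a chemokine receptor of tissue-resident lymphocytes, fell from 53.0 ± 12.3 to 5.22 ± 2.22 CPM while Cxcr5, Cxcr3 and Ccr7 were among those that rose. Ccr7, at 1.26 against 7.02 CPM (adjusted p = 0.0444), was not called by limma voom (0.0993) or without Id2-null replicate 1 or 2 or any WT replicate (0.0926 to 0.167). Il7r, which encodes the IL-7 receptor chain, was below the expression filter in the cultures, at 0.221 to 1.61 CPM.

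The receptor chains through which IL-15 signals did not pass the test. Il2rb, which encodes CD122, stood at 2925 against 3314 CPM (log2 fold change 0.18, adjusted p = 0.581) and Il2rg, the common gamma chain, at 680 against 615 CPM (-0.14, adjusted p = 0.741). In the list of IL-15 receptor, JAK and STAT genes, Stat4 alone was called of 11 members, and 3 were called when adjusted over the list alone (camera adjusted p = 0.096), and 2 with the replicate block, Il2ra besides (87.2 against 183 CPM, adjusted p = 0.00215 with the block). Stat4, a transcription factor activated by IL-12, rose from 279 ± 19.5 to 481 ± 24.3 CPM (log2 fold change 0.79, adjusted p = 0.00849). Of 16 inhibitors of cytokine signalling 1 rose and 0 fell, and 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.591). That member was Socs2, which went from 49.0 ± 3.53 to 97.0 ± 18.5 CPM (log2 fold change 0.98, adjusted p = 0.0128). Socs3 stood at 10.9 ± 4.0 against 22.4 ± 3.56 CPM, a log2 fold change of 1.03 (SE 0.28) with adjusted p = 0.0979, and passed the test with the replicate block (adjusted p = 0.0189). With the block 2 inhibitors were higher and 1 lower, the last being Cish (178 against 69.8 CPM, adjusted p = 0.0692, and 0.00159 with the block). DESeq2 called Socs3 (adjusted p = 0.0351), as did edgeR with no expression filter (0.0484) and without Id2-null replicate 3 (0.0263). Stat4 was not called without WT replicate 1 or 2 (adjusted p 0.0579 and 0.055), nor Socs2 without Id2-null replicate 1, WT replicate 1 or WT replicate 2 (adjusted p 0.0615, 0.0741 and 0.0728).

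Of 11 cytokine and chemokine genes 4 rose and 1 fell, and 4 and 2 when adjusted over the list alone (camera adjusted p = 0.473). With the replicate block 5 were higher and 2 lower, Tgfb1 among the latter (419 against 305 CPM, adjusted p = 0.0306 with the block). Il10, which encodes an anti-inflammatory cytokine, had counts of 36, 50 and 13 in Id2-null and of 0, 1 and 0 in WT libraries (adjusted p = 0.0101). Tnf rose from 27.2 ± 1.92 to 47.5 ± 8.39 CPM (adjusted p = 0.0386), and Ccl5, which encodes the chemokine RANTES, fell from 196 ± 23.2 to 78.4 ± 10.9 CPM (adjusted p = 0.00222). Il10 was not called without WT replicate 1 or 2 (adjusted p 0.0741 and 0.0646), nor Tnf without any 1 of the WT replicates or Id2-null replicate 1 (0.0862 to 0.199), with limma voom (0.0625) or with library sizes alone as scaling (0.0534). Among NK transcription factors 2 of 19, Foxo1 and Stat4, rose, and 3 rose and 1 fell when adjusted over the list alone. With the replicate block 3 were higher and 3 lower, the latter being Tbx21, Prdm1 and Zbtb32 (46.8 against 10.4 CPM for Zbtb32, adjusted p = 0.0452 with the block). That list had a median log2 fold change of 0.07 and a mean of -0.07 (camera adjusted p = 0.473). Eomes, a T-box factor of NK cells, stood at 470 against 543 CPM (adjusted p = 0.482).

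Genes of type 1 innate lymphoid cells (ILC1) and tissue residency were lower, 6 of 12 tested with 1 higher, and 7 and 2 when adjusted over the list alone (camera adjusted p = 0.000163, and adjusted p = 0.0829 with an estimated correlation). Tmem176b fell from 37.5 ± 2.92 to 6.61 ± 1.67 CPM (adjusted p = 0.000779), Cd200r1 from 36.9 ± 9.11 to 5.07 ± 1.21 CPM, and Itga1, which encodes the integrin CD49a, from 155 ± 3.89 to 65.7 ± 10.2 CPM. The member that rose was Itgae, which encodes the integrin CD103, at 1.59 against 7.07 CPM (adjusted p = 0.0372, 0.0502 with limma voom, and 0.0755 to 0.171 without Id2-null replicate 1 or 2 or WT replicate 1 or 2). Of the TGF-beta pathway 1 of 10 genes was called, also when adjusted over the list alone, with 1 fall besides (camera adjusted p = 0.261). Tgfb1 and Smad3 were called lower as well with the replicate block (adjusted p = 0.0306 and 0.0256). Tgfbr1 rose from 107 to 235 CPM (adjusted p = 0.0143), and not without Id2-null replicate 1 or WT replicate 1 or 2, where adjusted p was 0.0655 to 0.0783. Of 11 checkpoint and costimulation genes, Havcr2, which encodes TIM-3, fell from 55.6 ± 11.7 to 8.28 ± 6.54 CPM and Lag3 from 99.4 to 52.0 CPM. Havcr2 stood at 4.36, 4.65 and 15.8 CPM in Id2-null replicates 1 to 3. The adjusted p of Havcr2 and Lag3 was 0.042 and 0.0474, and 0.0518 and 0.0653 with the replicate block. Havcr2 was not called without Id2-null replicate 1 or 2 or any WT replicate, nor Lag3 without Id2-null replicate 2 or any WT replicate, with adjusted p of 0.114 to 0.175. Havcr2 was not called with no expression filter (adjusted p = 0.0986), nor Lag3 by limma voom (0.0533). The list's median log2 fold change was 0.31, its mean -0.06 and its camera adjusted p 0.909, with 2 higher and 4 lower when adjusted over the list alone. With the block 1 was higher, Cd28, and 1 lower, Icos (adjusted p = 0.0192 and 0.0321). Hes1, a target of Notch signalling, rose from 1.16 ± 1.02 to 21.9 ± 9.43 CPM (adjusted p = 0.0262), as 1 of 3 Notch genes by either adjustment (camera adjusted p = 0.473). Without Id2-null replicate 1 or 2 or WT replicate 1 or 2 its adjusted p was 0.0805 to 0.144, with limma voom 0.063 and with no expression filter 0.0507.

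The cell cycle list was lower as a set by camera (adjusted p = 8.69e-06), but did not pass with an estimated correlation (adjusted p = 0.651) or with fry (0.29). Its median log2 fold change was -0.31, and 0 of its 30 genes were called by edgeR, also when adjusted over the list alone, 0 by DESeq2 and 0 by limma voom. At unadjusted p under 0.05 there were 5. Mki67 stood at 1323 ± 80.2 in WT against 957 ± 307 CPM in Id2-null cells and Top2a at 1099 against 928 CPM. Without replicate 3 of both genotypes, the camera adjusted p was 0.0774, and the mean log2 fold change of the list went from -0.31 to -0.12. Against replicates 1 and 2 of its genotype, Id2-null replicate 3 was lower in 24 of the 30 genes and WT replicate 3 in 10. Of 20 apoptosis genes 1 fell, also when adjusted over the list alone (camera adjusted p = 0.805), and 2 with the replicate block, besides it Bcl2a1d, whose near-identical copies make its count uncertain (adjusted p = 0.0385). In edgeR without the replicate block, with all 6 cultures, no gene was called over all genes or over the list alone among 18 of glycolysis, 19 of cholesterol synthesis, 10 of nutrient transport, 10 of the integrated stress response, 13 of the interferon response and 12 immediate early genes. Of these 82 genes, 5 had an unadjusted edgeR p under 0.05, DESeq2 called 1, of nutrient transport, and limma voom 0. Camera adjusted p for these lists was 0.73, 0.672, 0.298, 0.619, 0.899 and 0.4. In the integrated stress response the median was -0.10 and the mean 0.01, and in the interferon response 0.09 and -0.11. Aldoa, a glycolytic enzyme gene, stood at 2404 ± 1452 against 2346 ± 1367 CPM, and in replicate 3 of both genotypes all 18 glycolysis and all 19 cholesterol synthesis genes were lower than in replicates 1 and 2. With the replicate block 1 glycolysis gene was lower, the glucose transporter gene Slc2a3 (300.5 against 116 CPM, adjusted p = 0.327, and 0.000245 with the block). Of the nutrient transport list 1 was then higher, the transferrin receptor gene Tfrc (392 against 684 CPM, adjusted p = 0.451, 0.00316 with the block and 0.000173 without replicate 3 of both genotypes), and 1 lower, Slc1a4 (17.0 against 6.36 CPM, 0.315 and 0.0385).

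**Figure D3:**
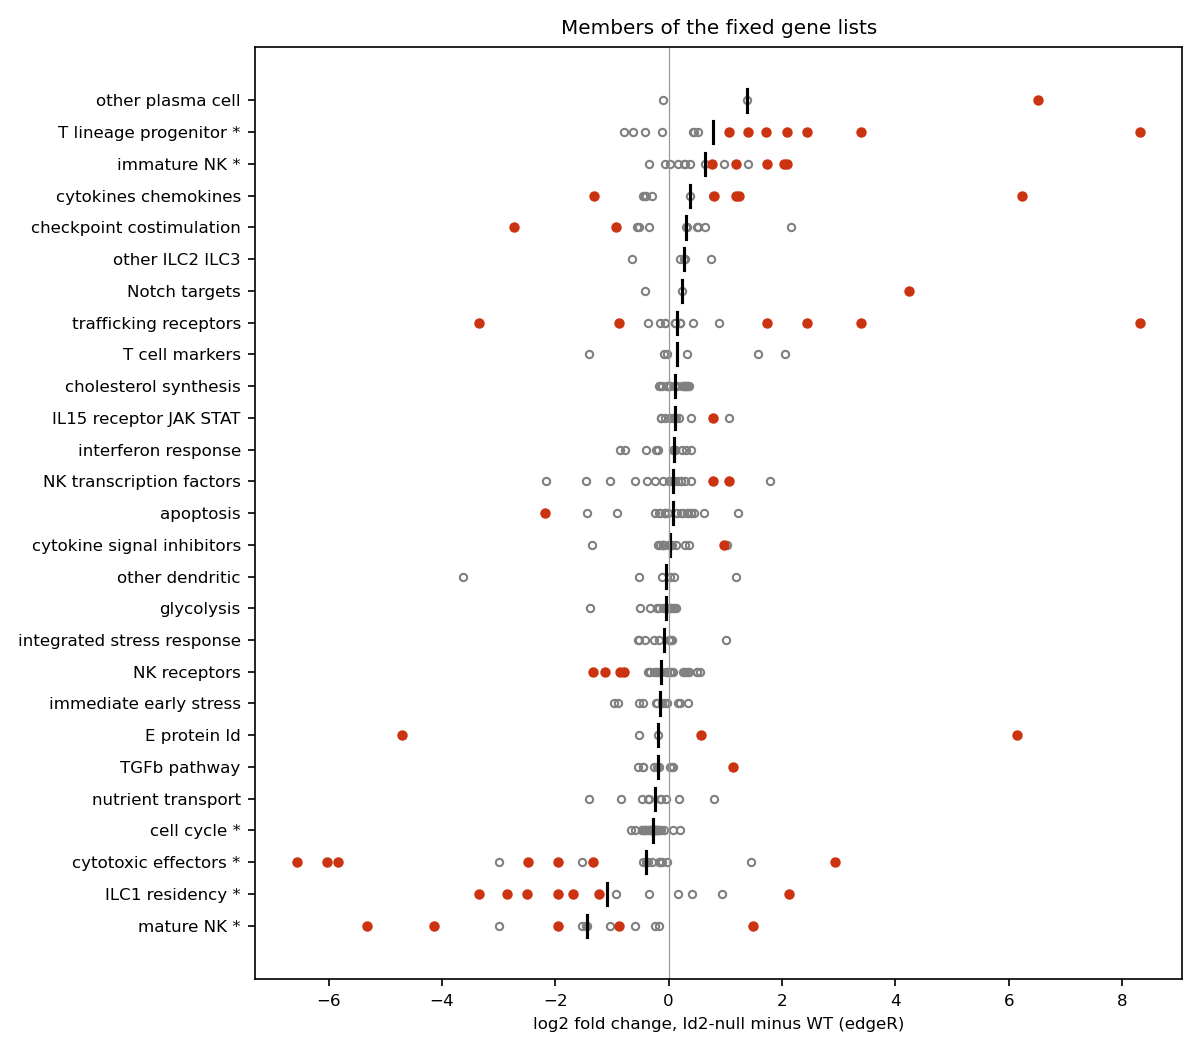
Log2 fold change of Id2-null minus WT cultures from edgeR (x axis) for each tested member of 27 gene lists (rows, in the order of their medians), with called genes as filled red points, other genes as open grey points, and the median as a black bar. Stars mark the 6 of these lists with a camera adjusted p under 0.05 at the preset correlation, none of which passed with an estimated correlation; the sex-linked list is not drawn.

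Few markers of other cell types passed the expression filter in the cultures, and most of those that did stood in the dendritic cell and ILC lists. The highest were Itgax, which encodes CD11c and is also found on mouse NK cells, at 474 against 484 CPM, and Kit at 378 against 456 CPM, neither called. Of the B cell list only Bank1 was tested, and it rose from 10.6 ± 6.22 to 39.9 ± 8.11 CPM (adjusted p = 0.0431), though not without Id2-null replicate 1 or 2 or WT replicate 2 or 3 (adjusted p 0.0965 to 0.15). Jchain, which encodes the joining chain of antibodies and stood in the plasma cell list, had counts of 41, 21 and 59 in Id2-null and of 1, 0 and 0 in WT libraries (adjusted p = 0.00335, list camera adjusted p = 0.156, 1 of 3 called by either adjustment). Of 6 dendritic cell genes edgeR called 0, with 2 at unadjusted p under 0.05, and 1 was lower when adjusted over the list alone (camera adjusted p = 0.479). DESeq2 and limma voom called 1 each, and edgeR with the replicate block 2 lower, Tcf4 and Xcr1 (adjusted p = 0.031 and 0.016). Of 5 ILC2 and ILC3 genes edgeR called 0 by either adjustment, with 1 at unadjusted p under 0.05, and DESeq2 and limma voom called 0 (camera adjusted p = 0.36). Pecam1, the only tested member of the stroma and endothelium list, fell from 157 ± 15.8 to 50.8 ± 11.4 CPM (adjusted p = 0.00202). Mcpt8, a basophil protease gene, stood at 18.9 against 5.82 CPM (adjusted p = 0.159, and 0.00532 with the replicate block), and DESeq2 called it (adjusted p = 0.0121). Cd68, a macrophage gene, stood at 18.3 against 8.48 CPM (adjusted p = 0.121, and 0.0458 with DESeq2). Bank1, Pecam1, Mcpt8 and Cd68, each the only tested member of its list, counted as 1 call when adjusted over the list alone. No neutrophil, erythroid or platelet gene passed the expression filter.

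The sorted Immature, M1 and M2 libraries were described without a test, since each population had 1 library and its differences have no replicate check. Ranges beside their values are exact Poisson 95% intervals that cover counting error only. Of 7480 genes with at least 20 CPM in the highest library, 1661 had levels that stepped down from Immature through M1 to M2 and 2042 had levels that stepped up. Immature cells had 263 genes at least 2-fold above M2, and M2 cells 302 at least 2-fold above Immature. Scaled by library size alone, the larger side turned, with 1987 stepping down and 1735 up, and 305 at least 2-fold higher in Immature against 273 in M2. Klrg1 stood at 9.77 CPM (7.01 to 13.3) in Immature, 39.1 CPM (33.5 to 45.3) in M1 and 813 CPM (786 to 840) in M2 cells, 83.2-fold higher in M2 than in Immature (61.2 to 116). Cx3cr1, the fractalkine receptor, went from 4.77 to 24.2 to 421 CPM, and Itgam from 50.5 to 974 to 1560 CPM. Entpd1 stood at 9.30, 98.6 and 251 CPM, Cma1 (a mast cell chymase) at 15, 214 and 698 CPM, and Ly6a2 at 11, 69.7 and 263 CPM. In the other direction, Tcf7 went from 983 CPM (953 to 1010) to 506 CPM (486 to 527) to 126 CPM (116 to 137). Ltb went from 426 to 152 to 51.5 CPM, Emb from 521 to 215 to 67.4 CPM, Kbtbd11 from 500 to 234 to 68.4 CPM and Il7r from 240 to 41.5 to 31.4 CPM. Tnni1, Hook1, Acpp, Pdcd1lg2 and Jaml, at 21.5 to 45.8 CPM in Immature cells, were 7.73 to 24.1-fold lower in M2.

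Of the 16 mature NK genes measured in the sorted libraries 15 were at least 2-fold higher in M2 than in Immature cells, with a median log2 difference of 2.55. That median lay at percentile 100 of 10000 random lists matched on expression, which describes these libraries only. The medians of the NK receptor, B cell, monocyte, neutrophil, and mast cell and basophil lists also lay at percentile 100. The markers of the sort are not given, so any listed genes used for it would differ by design. Gzmb went from 142 to 796 to 2070 CPM, Prf1 from 539 to 1710 to 2930 CPM and Tbx21 from 345 to 546 to 736 CPM. Of 15 immature NK genes 12 were at least 2-fold higher in Immature cells (median -2.02 as M2 minus Immature, percentile 0), Cd27 among them at 178, 132 and 35.5 CPM. Of 30 cell cycle genes 17 were at least 2-fold higher in Immature cells and 0 in M2 (median -1.18, percentile 0). Cytokine signal inhibitors were lower in M2 (median -0.37, percentile 0.18), with Socs2 at 15.5, 7.77 and 2.51 CPM and Socs3 at 69.6, 61.3 and 29.2 CPM. The IL-15 receptor list had a median of -0.12 at percentile 15.55. Gzmd, Gzme and Gzmg had 0 counts in all 3 sorted libraries, which allows up to 0.73 CPM in the Immature, 0.67 CPM in the M1 and 0.67 CPM in the M2 library. Markers of several other cell types were higher in M2. All 9 neutrophil genes measured, all 6 mast cell and basophil genes, 13 of 14 monocyte and macrophage genes and 8 of 10 B cell genes were at least 2-fold above Immature. The ILC2 and ILC3 list (median -0.92 as M2 minus Immature, percentile 0.51) and the T cell marker list (-0.48, percentile 1.06) went the other way. The neutrophil gene S100a8 stood at 25, 26.6 and 148 CPM, the myeloid gene Lyz2 at 53.2, 55.3 and 210 CPM, and the B cell gene Cd79a at 5.48, 5.33 and 23.7 CPM. The antibody genes Ighg2b and Igkv1-110 were among the 10 largest differences, with Ighg2b at 1, 9 and 114 counts, 109-fold higher in M2 (19.2 to 4340).

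Genes that set Immature and M2 cells apart were then followed in the cultures, which share no library with them. Of the 200 genes with the largest excess in Immature cells 186 were tested in the cultures, 20 of which rose and 3 fell in Id2-null cells (median log2 fold change 0.22, camera adjusted p = 0.000237, and adjusted p = 0.189 with an estimated correlation, or 0.234 with the replicate block besides). Of the 200 with the largest excess in M2 cells 65 were tested, 6 of which rose and 14 fell (median -0.76, camera adjusted p = 7.2e-09, and adjusted p = 0.139 with an estimated correlation, or 0.0289 with the replicate block besides). The other genes of the M2 set were below the expression filter in the cultures. Neutrophil, monocyte, B cell, and mast cell and basophil lists lay at percentile 100 in M2, as did the mature NK list. The M2 set may therefore mix genes of NK maturity with genes of other cells. The medians of the Immature and M2 sets were 0.34 and -1.68 with 100 genes each way, 0.12 and -0.24 with 500, and 0.48 and -1.68 at a minimum of 1 CPM. Without WT replicate 1 the Immature set had a median of 0.13. Tcf7, Cd27, Ltb and Nsg2 were higher in Immature than M2 cells and rose in Id2-null cultures. Klrg1, Gzmb, Entpd1 and Serpinb9b were higher in M2 than Immature cells and fell. Others went the opposite way: Tmem176b, Gzmc and Lag3 were 4.15, 2.62 and 2.18-fold higher in Immature than M2 cells and fell, while Ly6c2, Bank1 and Jchain were 3.5, 7.01 and 7.24-fold higher in M2 and rose. Gzmc rests on 25 against 10 counts (1.21 to 6.1-fold). Bank1 and Jchain stood in the B and plasma cell lists. Of 10 B cell genes measured, 8 were at least 2-fold higher in M2 and 1 in Immature, so the M2 levels of Bank1 and Jchain may include B cell RNA, which was not tested. The ILC1 list, with 6 members that fell in the cultures, had a median log2 difference of -0.70 as M2 minus Immature (percentile 0.13). The T-lineage progenitor list, which was higher in Id2-null cultures by camera at the preset correlation, had a median of -0.49 (percentile 0.05). Of its 16 measured members 6 were at least 2-fold higher in Immature and 0 in M2 cells, and it shares Tcf7 with the immature NK list. Of the 210 genes that rose, 97 were at least 1.5-fold higher in Immature cells and 25 in M2 cells. Of the 167 that fell, 25 were at least 1.5-fold higher in Immature and 62 in M2 cells. Over all genes tested these shares were 15.6% and 9.96%. Across the 11022 genes, which are not independent replicates, the genotype fold change and the Immature to M2 ratio had a Pearson correlation of 0.187 and a Spearman correlation of 0.121.

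**Figure D4:**
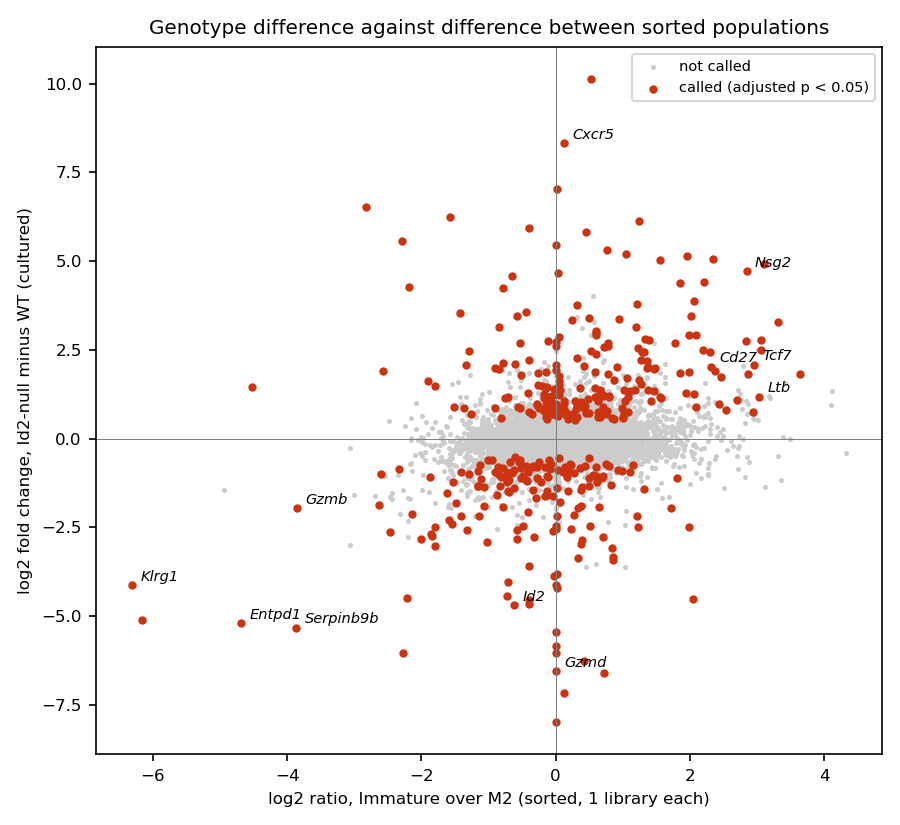
Log2 fold change of Id2-null minus WT cultures (y axis) against the log2 ratio of the Immature over the M2 library (x axis, 1 library each) for 11022 genes, with the 377 called genes in red. The Pearson correlation across genes was 0.187. Klrg1 and Entpd1 lie at the lower left, Tcf7 and Nsg2 at the upper right, and Cxcr5 near a ratio of 0. Gzmd lies at a ratio of 0 because it had 0 counts in both sorted libraries, which is not a measured equality.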

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

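Leaving out replicate 3 of both genotypes and leaving out X- and Y-linked genes were chosen after the data were seen. Calls between Id2-null and WT cultures, 210 higher and 167 lower, went to 316 and 264 with DESeq2, 452 and 383 with the replicate block, 78 and 56 at an adjusted p under 0.01, and 571 and 494 without replicate 3 of both genotypes. Leaving out 1 library gave 67 to 387 higher and 54 to 275 lower. Of the 377 genes, 121 to 371 were called with 1 library left out, 134 at an adjusted p under 0.01 and 310 to 377 in each other setting, with 0 signs changed in any. Id2 was called in each setting, at -4.44 to -5.20. With an estimated correlation 0 lists were higher and 0 lower, and the sets from the sorted libraries had medians of 0.22 (adjusted p = 0.189) and -0.76 (adjusted p = 0.139). Their medians ran from 0.12 to 0.48 and from -1.68 to -0.24 over all alternatives. With 1 library left out 6 to 8 lists were lower. With a minimum of 5 CPM, 582 genes were 2-fold higher in Immature and 608 in M2, since more genes were counted. The replicate block turned the sign of Aldoa (0) and Pkm (0.1), changed the calls of Tcf4, Tfrc, Mcpt8, Socs3, Tbx21, Prf1, Havcr2, Lag3 and Uty and of the list members given with a blocked value, and changed no other call of a named gene or list. Leaving out replicate 3 of both genotypes called Tcf4, Tfrc, Mcpt8, Socs3, Tbx21 and Prf1 and ended the call of Gzmd. Limma voom gave Pkm 0.1, and leaving out replicate 3 of both genotypes gave Shmt2 -0.15. Over all alternatives, named genes kept direction and side of the threshold 1295 times, lost a call 97 times, gained one 21 times and turned sign 21 times. Signs turned for uncalled genes with 1 library left out, over ranges of -0.47 to 0.37 for Aldoa, -0.47 to 0.39 for Pkm, -0.34 to 0.09 for Srebf2, -0.05 to 0.65 for Hmgcs1, -0.16 to 0.23 for Shmt2, -0.57 to 0.06 for Junb, -0.14 to 0.23 for Itgax and -0.11 to 0.76 for Kit. These genes were uncalled throughout, and the cause was not tested. At this depth a count of 0 still allows a level of up to 0.62 to 0.73 CPM.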

Other observations

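Genes outside the fixed lists also differed between Id2-null and WT cultures, and those given here were picked after their values were seen, among genes called in each of 17 other settings run at an adjusted p under 0.05. Il4ra and Il21r, which encode receptor chains for interleukin-4 and interleukin-21 and are neighbours on chromosome 7, rose from 184 ± 20.6 to 475 ± 65.5 CPM and from 118 ± 18.4 to 303 ± 39.8 CPM (SD, n = 3 each). Their adjusted p was 0.00202 and 0.00249 (edgeR). Mapk11 and Mapk12, neighbouring p38 kinase genes on chromosome 15, rose from 6.50 ± 1.95 to 45.7 ± 2.78 CPM and from 3.39 ± 1.00 to 37.6 ± 4.63 CPM. Lax1, an adaptor of lymphocyte signalling, rose from 184 to 430 CPM, Map3k8 from 23.2 to 71.8 CPM, and Aff3 from 17.9 ± 4.58 to 100.6 ± 11.1 CPM. Kbtbd11, which was 7.31-fold higher in Immature than in M2 cells, rose from 218 ± 46.2 to 770 ± 66.2 CPM (adjusted p = 0.00116). Lif, which encodes a cytokine of the interleukin-6 family, rose from 12.4 to 44.1 CPM.

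Among the genes that fell, Ifitm2, a membrane protein that restricts virus entry, went from 283 ± 33.5 to 34.7 ± 6.77 CPM (SD, n = 3 each, log2 fold change -3.03, SE 0.18, adjusted p = 0.000154, edgeR). Ltbp3, which binds latent TGF-beta, fell from 89.6 to 13.0 CPM, and the metallothionein gene Mt2 from 49.0 to 8.23 CPM. Cd55, a regulator of complement, fell from 290 ± 58.3 to 125 ± 4.65 CPM, and Capg, an actin-capping protein gene, from 302 to 133 CPM. Rbpj, the DNA-binding factor of the Notch pathway, fell from 118 to 61.8 CPM (adjusted p = 0.00429), while its target Hes1 rose.

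The tests of the sex split, of a batch behind replicate 3, of its depth and of B cell RNA were written after the results they measure were seen. In all 6 cultures Xist and the Y-linked transcripts matched female Id2-null and male WT animals, and the sorted libraries held both, with Xist at 82.3 to 119 CPM and Ddx3y at 33.7 to 42.6 CPM. Genes on the X chromosome other than Xist made up 2.92% of the calls and 3.13% of the genes tested (Fisher's exact test, p = 1). That share is a description only and does not measure an effect of sex on X-linked or other genes. Effects of sex and of Id2 on the other genes cannot be told apart, because 0 libraries separated sex from genotype. Id2 itself, the target, is set by the genotype label.

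Replicate 3 of both genotypes lay apart from replicates 1 and 2, with all 18 glycolysis genes and all 19 cholesterol synthesis genes lower in each (medians of -1.58 and -1.28 in Id2-null and -1.91 and -1.19 in WT, log2). Among 6113 genes over a log2 CPM of 5, 84 were at least 2-fold lower in replicate 3 of both genotypes and 10 higher, with 1 opposite. Vegfa, Bnip3 and Egln3, known targets of the hypoxia response, were at -2.69, -2.41 and -1.71 in Id2-null and at -4.20, -3.87 and -4.12 in WT. They were picked from the genes with the largest shared falls, and no list of hypoxia genes was tested. Lower depth is argued against by WT replicate 3, which had 103% of the mean total of WT replicates 1 and 2. A trend with gene length, as degraded RNA can give, is argued against by a length correlation of 0.07 in Id2-null and -0.006 in WT. Gene totals cannot show other signs of degraded RNA. The deviations of both replicate 3 libraries correlated at 0.42, which restates that they stand apart together and does not show why. A shared culture day or batch may account for the replicate 3 difference, but the labels give no batch, and medium or oxygen in culture was not tested.

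Ighm, the constant region gene of immunoglobulin M (chromosome 12, positions 113418826 to 113422730), rose from 141 ± 28.4 to 936 ± 192 CPM in Id2-null cultures (adjusted p = 0.000422, edgeR). B cells in these cultures are argued against by Cd79a, Cd79b and Ms4a1, which together reached at most 0.185% of the Ighm level in the 3 Id2-null libraries, and Igkc stayed at or under 0.892 CPM by library size alone. Pou2af1, a coactivator of immunoglobulin genes, rose from 0.418 to 8.58 CPM (adjusted p = 0.00726). Transcription of the unrearranged Ighm locus in NK cells that lack ID2 is a hypothesis that stays open, since gene totals do not show where transcripts start. Sex stays open here as well.

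The 6 cultures can be split 3 against 3 in 10 ways, so that the share of splits with a result as large is never under 0.05. The genotype split called 377 genes, the only 1 of 10 to do so, and the highest other split called 0. Every other split puts libraries of both genotypes on each side, which adds the genotype difference to the spread within sides. Few calls then follow whatever the cause, so the contrast of 377 with 0 cannot decide. The genotype split is also the split by sex. For the gene lists, 2 of 10 splits called as many as the real 7, and the highest other, with 7, set Id2-null replicates 1 and 3 and WT replicate 3 against the rest. The difference of the medians of the Immature and M2 sets was 0.987 for the genotype, as large in 1 of 10 splits, with 0.719 as the highest other. Of the 10 splits, 4 part all 3 same-numbered pairs, and the other 3 of these called 0 genes and at most 3 lists.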
